A study of Mus musculus with 9 samples.

How the data were processed

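Total RNA was extracted from powdered liver and depleted of ribosomal RNA, and libraries were sequenced on an Illumina NextSeq instrument, per the labels' protocols. The 9 libraries fall into 3 groups of 3 by their titles and treatment labels: ground control (GC), microgravity (MG) and artificial gravity in flight (AG). Depletion of ribosomal RNA keeps transcripts that are not polyadenylated and unspliced transcripts, so reads in introns are part of the data.

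The authors deposited 1 table for the series with 49585 gene rows. Per the file headers it gives for each gene and library whole-number read counts, split into unique and total reads in exons, introns and exon junctions, beside expression values. The deposited expression values are whole counts, and in every gene and library they equal the unique exon reads plus the multiply mapped reads over exon junctions. RPKM values deposited by the authors were used only to work out how many mapped reads each library had. Fold changes and p-values of the authors' own comparisons, with their adjusted p-values, are in the deposited table and were used only to count how many genes it marks. The submitters' processing notes name the builds GRCm38 and mm10, and the aligner, the counting tool and their versions are not given in the sources used here. Whether counting used the strand of the reads is not given either. The table holds 135 other columns of per-library values that were not used here.

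The expression values were the counts tested. Their totals per library were between 6194521 and 8957331, and 30904 rows had no reads in any library. A level of 3 reads corresponds to between 0.335 and 0.484 CPM, depending on the library. Reads without molecular identifiers are not independent molecules, so such a floor covers counting error only.

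Genes were kept with edgeR's filterByExpr by group, which left 11884. Counts were scaled by TMM and fitted by edgeR's quasi-likelihood model with 1 mean per group over all 9 libraries, which leaves 6 residual degrees of freedom, and the groups were compared with glmQLFTest. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. Flight vs GC is the mean of MG and AG minus GC. CPM use library totals scaled by TMM, and log2 CPM for list tests had a prior count of 2. The biological coefficient of variation was 16.7%.

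Before the data were examined, the comparisons, tests, gene lists, alternatives and the rule for named genes were fixed. There were 42 gene lists, 11 of them markers of cell types or other tissues, and 38 had at least 4 tested members. Lists were tested by camera from limma with a preset correlation of 0.01 between genes, beside camera with the correlation estimated from the libraries and fry, with Benjamini-Hochberg adjustment over the lists of each comparison. For each of the 3 pairwise comparisons the rule names up to 6 genes with the largest change each way among called genes whose libraries do not overlap and whose mean count in the higher group is at least 50, leaving out predicted and unnamed genes. It further names up to 4 members of each list that camera calls or that has at least 3 called members, by smallest p, 12 fixed genes in every case, and the 5 genes with the smallest p where none is called.

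The shared GC libraries were handled by 20 simulations of groups without change. The tests were checked on simulated counts drawn from the means, dispersions and library sizes of these samples for 11884 genes, a random part of them changed. For MG vs GC, 15.2% of genes changed 1.5-fold, 72.2% changed 2-fold and 93.5% changed 4-fold were recovered, with 6 false calls among 126. For AG vs GC the shares were 18.3%, 70.8% and 89.7%, with 12 false calls among 135, and for MG vs AG 23.5%, 66.1% and 86.3%, with 4 among 122. A list shifted by -0.5 on the log2 scale was found in the simulation of MG vs GC, with 0 other lists called. All simulations here drew genes independently of each other, so this one cannot show how often lists of genes that move together are called falsely. Splits of the MG and GC libraries that mixed both groups called up to 14 lists by camera.

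Alternatives were RLE, upper quartile or no scaling, other filters, DESeq2, limma-voom, edgeR's robust setting, fits of only the groups compared, a block for the library number, stricter thresholds, leaving out the genes that take most counts, and leaving out each library in turn. Those prepared for a table of normalized values only did not apply. Added after seeing the data were unique or total exon reads, edgeR's exact test without a filter, the muscle markers as a covariate, leaving out 3 libraries, a model with flight as 1 group, and a correction of each library for GC content and transcript length, for which 11876 tested genes (99.9%) had values. The computation used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.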

Results

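Gene expression was measured by RNA sequencing in the livers of male C57BL/6J mice aged 14 weeks that had lived for about 35 days under 1 of 3 conditions. Mice of the MG group were housed in microgravity on the International Space Station. Mice of the AG group were housed beside them in a centrifuge turning at 77 rpm, which gave 1 g in orbit. Mice of the ground control group, GC, were kept at 1 g in Tsukuba in matching housing. There were 3 libraries per group, 9 in all, from flight groups that held 6 animals each. Flight mice were taken for analysis 2 days after splashdown, so the livers reflect the flight, the landing and the days after it together. The flight mice and the ground mice came from different suppliers, so every comparison with GC also compares suppliers. The labels do not say which animal each library came from, and p-values measure the spread between these libraries, which may be technical in part.

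The libraries held between 6194521 (GC 2) and 8957331 (MG 1) gene counts, and 11884 genes had enough reads to be tested. Levels are given as CPM (counts scaled to a common library total), mean ± SD over the 3 libraries of a group, and changes as log2 fold changes ± standard error (SE). On the first principal component, which held 28.4% of the variance, AG 1 lay farthest from the other libraries at -36.75, and it was also the lowest on the second component at -35.66. Skeletal muscle transcripts were present in some libraries of each group: the mean log2 deviation of 10 muscle markers was 2.69 in GC 1, 4.13 in GC 2, 3.61 in MG 2 and 1.55 in AG 1, and between -2.92 and -0.72 in the other 5. Macrophage transcripts were high in AG 1 alone, with a mean log2 deviation of 1.72 against -0.43 to -0.06 in the other 8 libraries.

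**Figure D1:**
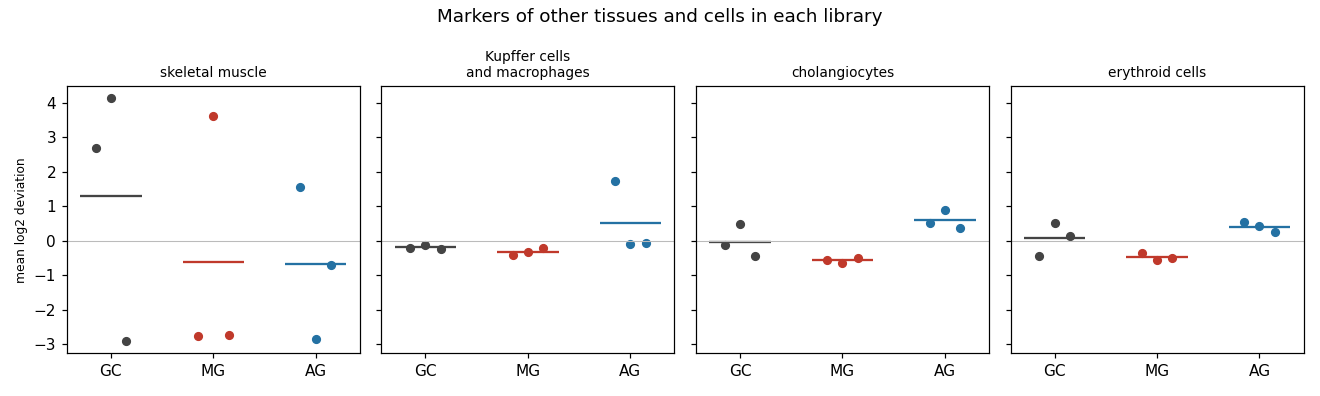
Markers of skeletal muscle, macrophages, bile duct cells and erythroid cells in each of the 9 libraries. Each point is 1 library (y axis: mean over the list of log2 CPM minus the gene's mean over all libraries) and each bar the mean of a group; muscle markers were highest in GC 2 at 4.13 and macrophage markers in AG 1 at 1.72.

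The comparison of MG with GC asks how the liver of mice living in microgravity differed from that of mice on the ground. In MG livers 8 of 18 genes of fatty acid and triglyceride synthesis and 5 of 24 genes of cholesterol synthesis and uptake fell, while 5 of 27 genes of fatty acid oxidation rose and 1, Fabp1, fell. Camera called these lists with its preset correlation but not with an estimated correlation (adjusted p = 0.306, 0.359 and 0.389). Scd1, the desaturase that makes monounsaturated fatty acids, fell from 6070 ± 541 CPM (SD, n = 3) to 1199 ± 410 CPM (SD, n = 3), a log2 fold change of -2.34 ± 0.30. Apoa4, which encodes an apolipoprotein, rose from 71.3 ± 32.4 CPM to 708 ± 209 CPM, a log2 fold change of 3.31 ± 0.40. Of 14 genes typically higher in the male than in the female liver 10 fell (camera adjusted p = 0.219 with an estimated correlation), among them Cyp7b1, an oxysterol hydroxylase, from 317 ± 17.9 CPM to 115 ± 22.3 CPM.

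In all, 65 genes rose and 100 fell in MG vs GC at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, and 79 of these 165 changed at least 2-fold. The MG and GC libraries did not overlap for any of the 165. Over all 11884 genes they did not overlap for 23.2%, where chance gives 10%. Among genes with a mean count of at least 50 in the higher group, other large changes included those of Acot3, an acyl-CoA thioesterase (log2 fold change 2.68 ± 0.40), the fatty acid hydroxylase Cyp4a14 (2.52 ± 0.39), the cytokine signalling inhibitor Socs2 (2.11 ± 0.42), Gadd45g (2.02 ± 0.37) and the peroxisomal transporter Abcd2 (1.88 ± 0.26), which rose. Selenbp2 (-3.77 ± 0.78), the lipogenic regulator Thrsp (-2.74 ± 0.57), the protease inhibitor Serpina1e (-2.59 ± 0.38) and the complement gene C4a (-2.24 ± 0.43) fell. The authors' deposited table marks 226 genes as changed between GC and MG, 151 of them among the 165.

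Gene positions follow the deposited table, whose processing notes name the mouse builds GRCm38 and mm10. Apoa4 (ENSMUSG00000032080) lies on chromosome 9 from 46240696 to 46243459, Scd1 (ENSMUSG00000037071) on chromosome 19 from 44394451 to 44407709, Cyp4a14 (ENSMUSG00000028715) on chromosome 4 from 115486200 to 115496142 and Cyp7b1 on chromosome 3 from 18071950 to 18243338. These are gene bodies, and the counts are of reads in their exons. Counts are uncertain for genes that share reads with near copies. Uniquely mapped reads made up 46.9% of the total exon reads of Apoa4, 61.9% for Selenbp2, 75.1% for Serpina1e, 57.8% for Cyp4a12b, 50.4% for Lcat, 21.2% for Gsta1, 7.24% for Ugt1a1, 42.8% for mt-Nd4, 33.8% for Hspa1b and 5.23% for Hba-a2. The counts tested leave out multiply mapped reads other than those over exon junctions. With unique exon reads alone, 48 of 49 calls of named genes in edgeR's test were kept. Without a stated use of strand, reads could not be told apart where a gene overlaps an antisense neighbour, as Acss2 does with Gss, Abcg5 with Abcg8, Ccnd1 with Oraov1, Alas2 with Apex2, mt-Nd6 with mt-Nd5 and Hspd1 with Hspe1.

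**Figure D2:**
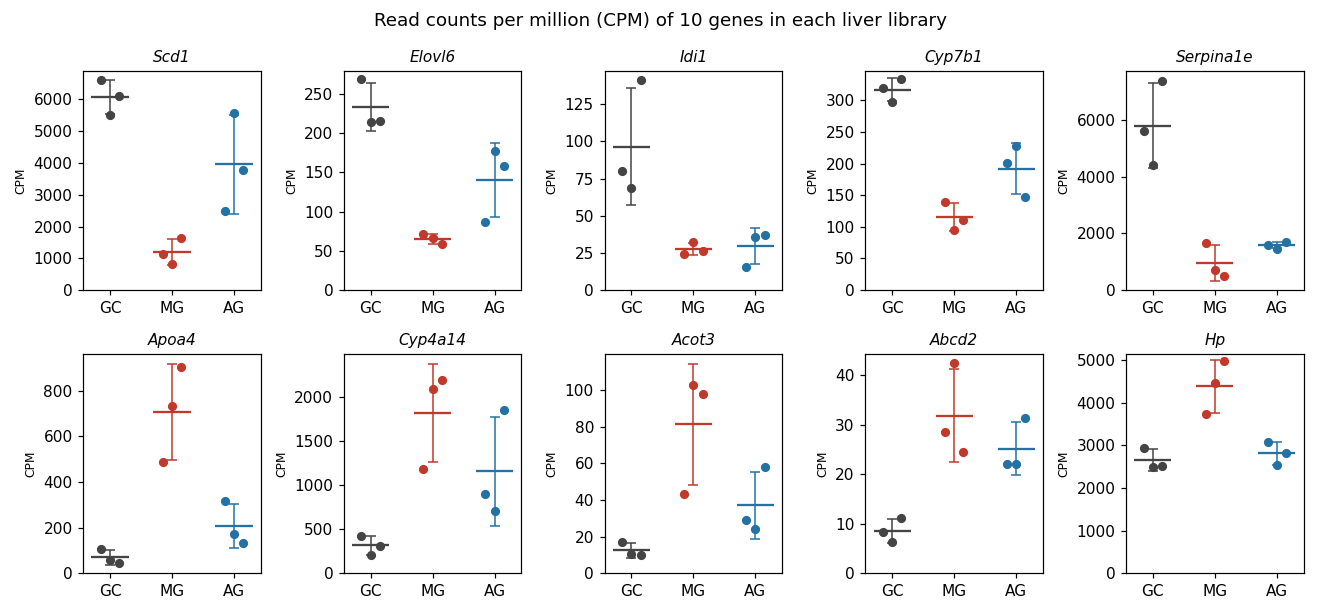
CPM of 10 genes in each library of GC, MG and AG (y axis, linear, from 0). Points are libraries, horizontal bars are group means and error bars are 1 SD; Scd1 averaged 6070 CPM in GC, 1199 in MG and 3956 in AG, while Hp averaged 2655, 4388 and 2813.

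Of 24 tested genes of cholesterol synthesis and uptake, 5 fell in MG vs GC and 19 were not called, with 15 lower when adjusted over the list alone. Among them were the synthesis enzymes Pmvk (-1.45 ± 0.23), Idi1 (-1.81 ± 0.32) and Dhcr7 (-1.61 ± 0.29), and Msmo1 (-2.12 ± 0.43). The median log2 fold change of the list was -1.07 and all 24 values were negative. On this list camera gave an adjusted p of 7.94e-14 (adjusted p = 0.359 with an estimated correlation). Of 18 genes of fatty acid and triglyceride synthesis, 8 fell, 0 rose and 10 were not called, with 11 lower when adjusted over the list alone. They included Elovl6, which elongates palmitate (-1.83 ± 0.22), Scd1, Acss2 (-1.04 ± 0.18) and Acaca, the acetyl-CoA carboxylase (-0.99 ± 0.17). Here camera gave an adjusted p of 1.76e-10 (adjusted p = 0.306 with an estimated correlation). Of 27 genes of fatty acid oxidation and PPAR-alpha targets, 5 rose, 1 fell and 21 were not called, with 14 higher and 1 lower when adjusted over the list alone. Cyp4a14, Vnn1 (1.56 ± 0.27), the fatty acid carrier Cd36 (0.99 ± 0.16), Acadm (0.70 ± 0.13) and Acadl (0.54 ± 0.09) rose, while Fabp1, the liver fatty acid binding protein, fell (-1.11 ± 0.19). For this list camera gave an adjusted p of 4.73e-08 upward (adjusted p = 0.389 with an estimated correlation). In the mean of this list MG 1, at -0.17, lay below GC 1, at -0.10, while MG 2 (0.55) and MG 3 (0.38) lay above every GC library. Msmo1, Acadm and Acadl fall outside the rule for named genes and were added after their values were seen, as were others named because their count was 5 or fewer.

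By camera, though not by fry, male-biased liver genes were the list with the smallest p in MG vs GC. Of 14 tested members 10 fell and 4 were not called, with 11 lower when adjusted over the list alone. All 14 values were negative, with a median of -1.05. Cyp4a12b (-1.54 ± 0.18), Cyp7b1 (-1.46 ± 0.17), the complement gene C6 (-0.95 ± 0.14) and Cyp2d9 (-0.82 ± 0.13) were among those that fell. For this list camera gave an adjusted p of 6.95e-15 (adjusted p = 0.219 with an estimated correlation). The female-biased list had 16 genes, of which only 8 were tested, so its results cover these alone. Of the 8, Abcd2 and Acot3 rose and 6 were not called, with 6 higher when adjusted over the list alone. Fmo2 stood at 1.15 ± 0.35 without passing the test. Camera gave the list an adjusted p of 7.19e-05 (adjusted p = 0.359 with an estimated correlation). In the mean of the male-biased list, the 3 GC libraries lay between 0.54 and 0.76 and the 3 MG libraries between -0.83 and -0.46.

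**Figure D3:**
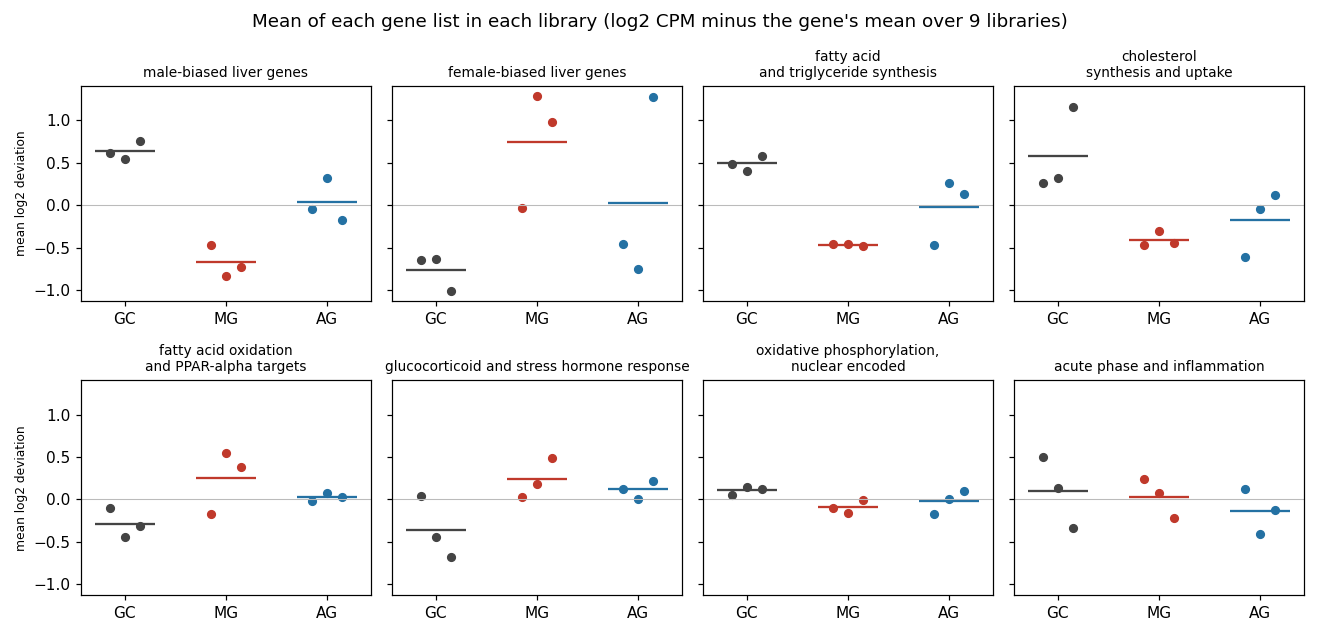
Mean of 8 gene lists in each library. The y axis is log2 CPM minus each gene's mean over the 9 libraries, points are libraries and bars are group means; the male-biased list averaged 0.64 in GC, -0.68 in MG and 0.03 in AG.

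A few genes of mitochondrial respiration and of antigen presentation also fell. Of 25 nuclear genes of oxidative phosphorylation, Cox5b (-0.64 ± 0.10) and Ndufb3 (-0.51 ± 0.09) fell and 23 were not called, with 4 lower when adjusted over the list alone. For these, camera gave an adjusted p of 1.24e-05 (adjusted p = 0.467 with an estimated correlation). Of the 13 genes encoded in the mitochondrial genome, mt-Nd4 fell (-0.92 ± 0.19) and 12 were not called, with 4 lower when adjusted over the list alone, and the camera adjusted p was 1.24e-05 (adjusted p = 0.359 with an estimated correlation). Of 17 antigen presentation genes, H2-Q6 (-0.95 ± 0.17) and H2-Aa (-1.12 ± 0.23) fell and 15 were not called, with 6 lower when adjusted over the list alone, at a camera adjusted p of 8.28e-05 (adjusted p = 0.449 with an estimated correlation). None of 24 interferon response genes was called, over all genes or adjusted over the list alone, but 23 values were negative, such as Bst2 at -0.55 ± 0.17 and Cxcl9 at -0.92 ± 0.36. Camera gave that list an adjusted p of 0.00083 (adjusted p = 0.522 with an estimated correlation).

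Camera called 8 more lists with its preset correlation. Of 18 glucocorticoid and stress hormone genes, Hsd11b1, which regenerates active glucocorticoid, rose (0.70 ± 0.09) and 17 were not called, with 3 higher when adjusted over the list alone (camera adjusted p = 0.000983, and adjusted p = 0.359 with an estimated correlation). None of 20 iron and heme genes was called, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00633, and adjusted p = 0.359 with an estimated correlation). Bmp6 stood at 0.87 ± 0.20 and Slc40a1, the iron exporter, at 0.77 ± 0.18. Of 17 cell cycle genes Ccnd1, cyclin D1, fell (-1.22 ± 0.21) and 16 were not called, also when adjusted over the list alone (camera adjusted p = 0.00661, and adjusted p = 0.359 with an estimated correlation). Of 6 erythroid genes Alas2, which starts heme synthesis in red cells, fell (-0.92 ± 0.14) and 5 were not called, also when adjusted over the list alone (camera adjusted p = 0.00633, and adjusted p = 0.359 with an estimated correlation). None of 15 heat shock genes was called, with 2 lower when adjusted over the list alone (camera adjusted p = 0.00862, and adjusted p = 0.568 with an estimated correlation). None of 23 urea cycle and amino acid genes (camera adjusted p = 0.00862, and adjusted p = 0.747 with an estimated correlation) and none of 7 bile duct markers (camera adjusted p = 0.0085, and adjusted p = 0.359 with an estimated correlation) was called, over all genes or adjusted over the list alone, and both lists were lower. Of 4 genes known to differ between C57BL/6 substrains, Nnt, the mitochondrial transhydrogenase, rose from 54.5 ± 2.32 CPM to 87.6 ± 3.30 CPM and 3 were not called, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00633, and adjusted p = 0.306 with an estimated correlation). Together with the 9 lists above, these made 17 of 38 tested lists, 5 upward and 12 downward, called by camera with its preset correlation, and 0 of the 17 held with an estimated correlation.

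Lists that camera did not call also held changed genes in MG vs GC. Of 20 lipoprotein genes 4 rose, Apoa4, Lipc (0.55 ± 0.09), Lcat (0.51 ± 0.09) and Abcg5 (0.56 ± 0.11), and 16 were not called, with 6 higher when adjusted over the list alone (camera adjusted p = 0.101, and adjusted p = 0.359 with an estimated correlation). Of 25 Nrf2 targets and antioxidant genes 4 fell and 21 were not called, with 2 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.104, and adjusted p = 0.49 with an estimated correlation). They were the pentose phosphate enzymes Tkt (-0.64 ± 0.10) and Pgd (-0.88 ± 0.16) and the glutathione transferases Gstm3 (-1.67 ± 0.33) and Gsta1 (-2.72 ± 0.56). Of 21 xenobiotic metabolism genes, Cyp3a25 (0.74 ± 0.10) and Ugt1a1 (0.68 ± 0.12) rose, Cyp1a2 (-0.85 ± 0.13) and Cyp2c55 (-2.09 ± 0.33) fell and 17 were not called, with 7 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.115, and adjusted p = 0.747 with an estimated correlation). Of 22 acute phase genes, Hp, haptoglobin (0.72 ± 0.13), Lbp (0.87 ± 0.15) and Cp, ceruloplasmin (0.60 ± 0.10) rose, Orm1 fell (-0.81 ± 0.14) and 18 were not called, with 5 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.205, and adjusted p = 0.84 with an estimated correlation). The median of that list was 0.23 and its mean -0.11, and the direction given by camera was upward. Among genes fixed for report in every case, Gclc (0.80 ± 0.17), Fgf21 (2.15 ± 0.62), Pck1 (0.68 ± 0.23), Cdkn1a (1.64 ± 0.76), Cyp2b10 (1.78 ± 0.71), Saa1 (-2.25 ± 0.58), Cyp7a1 (-0.86 ± 0.68), Per2 (-0.35 ± 0.16), Col1a1 (-1.24 ± 0.44) and Cbs (0.05 ± 0.12) did not pass the test in MG vs GC.

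The number of changed genes in MG vs GC depended on single libraries: it was 52 without GC 1, 21 without GC 2, 51 without GC 3, 108 without MG 1, 28 without MG 2, 63 without MG 3, 290 without AG 1 and 273 without AG 3. In each of these 9 fits, including the one without AG 2, Apoa4, Cyp4a12b, Cyp7b1, Elovl6 and Scd1 were among the genes called. Without the 3 libraries richest in muscle transcripts (GC 1, GC 2 and MG 2), a set chosen after seeing the data, 0 genes were called by the same edgeR test with 1 GC library left. The median ratio of the fold changes of the 165 genes to those from 9 libraries was 0.973. Muscle markers themselves were -0.96 in the median in MG vs GC with 0 of 10 called, also when adjusted over the list alone (camera adjusted p = 0.104, and adjusted p = 0.809 with an estimated correlation).

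List calls in MG vs GC that ended when 1 library was left out were those of cell cycle genes (camera adjusted p = 0.0609 without GC 3, range 0.00139 to 0.0609 over 15 alternatives), heat shock genes (0.132 without GC 3, range 0.000908 to 0.132), erythroid genes (0.0623 without GC 2, range 1.27e-06 to 0.0623) and urea cycle genes (0.392 without MG 2, range 4.39e-05 to 0.392). Without GC 1, GC 2 and MG 2 together, 12 of the 17 calls in MG vs GC were kept, in a fit where GC had 1 library and the spread came from MG and AG libraries only. Those that ended were the calls of interferon response genes (camera adjusted p = 0.0871, range 4.34e-05 to 0.0871), iron and heme genes (0.113, range 0.00112 to 0.113), bile duct markers (0.729, range 0.000465 to 0.729), substrain genes (0.166, range 0.00292 to 0.166) and urea cycle genes (0.259).

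The comparison of AG with GC asks how mice that flew, but under 1 g, differed from mice on the ground. No single gene passed the threshold. The same lists of cholesterol and fatty acid synthesis genes were called downward by camera as in MG, and the macrophage markers upward through 1 library, AG 1. With an estimated correlation none of these calls held (camera adjusted p = 0.701, 0.701 and 0.788), and fry called 0 lists. The gene with the smallest p was Mup16, a major urinary protein gene, at 180 ± 18.6 CPM (SD, n = 3) in AG and 418 ± 38.9 CPM (SD, n = 3) in GC, with 8.28% of its exon reads mapped uniquely. Mup16 was also among the genes called lower in MG vs GC, with a log2 fold change of -1.23, so its lower level was not particular to AG.

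In edgeR's quasi-likelihood test 0 genes were changed in AG vs GC, with 1199 genes at an unadjusted p below 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.112. DESeq2 called 118, limma-voom 0, edgeR's exact test without a filter 73, and the authors' deposited table marks 54. Libraries of AG and GC did not overlap for 14.4% of genes, where chance gives 10%. The 5 genes with the smallest p, none of them called, were Mup16 (-1.22 ± 0.17), the transporter Slc16a7 (0.82 ± 0.12), Mup2 (-1.79 ± 0.27), Pmvk (-1.55 ± 0.24) and Fam25c (-1.27 ± 0.20). Of the fixed genes, Cyp4a14 stood at 1.87 ± 0.38, Saa1 at -2.55 ± 0.59, Cdkn1a at 1.60 ± 0.76, Cyp2b10 at 1.45 ± 0.72, Fgf21 at 0.86 ± 0.68, Pck1 at 0.75 ± 0.23, Gclc at 0.58 ± 0.17, Nnt at 0.33 ± 0.09, Per2 at 0.09 ± 0.16, Cyp7a1 at 0.07 ± 0.68, Cbs at -0.14 ± 0.12 and Col1a1 at -0.29 ± 0.42. In the 9 fits that left out 1 library, the count was 60 without AG 3 and 0 without GC 1 or GC 3. It was 3 without MG 2 (Gadd45g, Mup1 and Mup14), 2 without AG 2 (Mup17 and Serpina6), and 1 without GC 2 (Dmbt1), MG 1 (Serpina1e), MG 3 (Mup16) or AG 1 (Fam25c).

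By camera, 11 of 38 lists were called in AG vs GC, 6 upward and 5 downward, and 0 with an estimated correlation. All 24 genes of cholesterol synthesis and uptake had negative values with a median of -0.76, 0 were called, and 12 were lower when adjusted over the list alone (camera adjusted p = 1.36e-11, and adjusted p = 0.701 with an estimated correlation). Idi1 stood at -1.70 ± 0.33 and Nsdhl at -1.53 ± 0.34. On this list GC 3 stood apart with a mean log2 deviation of 1.16, against 0.26 in GC 1 and 0.32 in GC 2, and without GC 3 the camera adjusted p was 1.02e-05 (range over 15 alternatives 1.26e-27 to 1.02e-05). GC 3 enters MG vs GC in the same way, where the camera adjusted p without it was 1.38e-09 (range 2.19e-31 to 1.38e-09). Of 18 fatty acid and triglyceride synthesis genes 0 were called, with 1 higher and 7 lower when adjusted over the list alone (camera adjusted p = 2.52e-05, and adjusted p = 0.701 with an estimated correlation). Acacb stood at -1.40 ± 0.32 and Me1 at -0.70 ± 0.16. Of 27 genes of fatty acid oxidation 0 were called, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.000621 upward, and adjusted p = 0.788 with an estimated correlation). Vnn1 stood at 1.05 ± 0.27. All 14 male-biased genes were negative with a median of -0.35, 0 called and 2 lower when adjusted over the list alone (camera adjusted p = 1.19e-06, and adjusted p = 0.633 with an estimated correlation). C6 stood at -0.63 ± 0.14. Of 8 female-biased genes 0 were called, with 2 higher when adjusted over the list alone (camera adjusted p = 0.0142, and adjusted p = 0.752 with an estimated correlation). Abcd2 stood at 1.54 ± 0.26. The mean of the female-biased list was 1.28 in AG 3 but -0.46 in AG 1 and -0.75 in AG 2.

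Of 18 glucocorticoid and stress hormone genes 0 were called in AG vs GC, with 4 higher when adjusted over the list alone (camera adjusted p = 0.000101, and adjusted p = 0.633 with an estimated correlation). Hsd11b1 stood at 0.57 ± 0.09 and Dusp1 at 0.72 ± 0.16. Of 21 xenobiotic metabolism genes 0 were called, with 1 higher when adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.701 with an estimated correlation). Cyp3a25 stood at 0.61 ± 0.10. Of 25 nuclear oxidative phosphorylation genes 0 were called, with 2 lower when adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.788 with an estimated correlation). Ndufb3 stood at -0.42 ± 0.09. Of 16 p53 targets 0 were called, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.752 with an estimated correlation). Gdf15 stood at 1.16 ± 0.27. Of 23 urea cycle and amino acid genes 0 were called, with 1 lower when adjusted over the list alone (camera adjusted p = 0.0449, and adjusted p = 0.79 with an estimated correlation). Asns stood at -2.07 ± 0.45. Of 12 macrophage markers 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.00329, and adjusted p = 0.788 with an estimated correlation). Marco, a scavenger receptor of macrophages, stood at 278 CPM in AG 1, 3.23 CPM in AG 2 and 5.98 CPM in AG 3, and Adgre1 at 137, 15.5 and 21.1 CPM. The 10 muscle markers, not called as a list, had a median of -3.03 in AG vs GC, with 0 called, also when adjusted over the list alone. Camera gave them an adjusted p of 0.0804 (adjusted p = 0.79 with an estimated correlation).

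AG 1 was also the lowest AG library in fatty acid and triglyceride synthesis genes, at -0.47 against 0.26 in AG 2 and 0.13 in AG 3, and in cholesterol genes, at -0.61 against -0.05 and 0.13. Without it the camera adjusted p of these lists was 0.00478 (range 1.36e-07 to 0.00478) and 1.91e-06. Without AG 1, the library rich in macrophage transcripts, 7 of the 11 list calls in AG vs GC remained. Camera then gave adjusted p = 0.178 for macrophage markers (range over 15 alternatives 0.000151 to 0.178), 0.254 for oxidative phosphorylation (0.000357 to 0.254), 0.106 for p53 targets (0.0172 to 0.106) and 0.653 for urea cycle genes (0.000327 to 0.653), whose direction was then upward. Without AG 3, the call ended for female-biased genes (camera adjusted p = 0.586, range 0.000301 to 0.586), xenobiotic genes (0.177, range 1.91e-06 to 0.177) and p53 targets (0.0785). The p53 call also ended without GC 1 (0.0936), GC 3 (0.0764) or MG 2 (0.0562), and the urea cycle call without GC 1 (0.167), GC 3 (0.0972) or MG 1 (0.0544), all by camera. With all libraries kept, camera lost the p53 call with the library number as a block (0.0687) and the urea cycle call after the GC content and length correction (0.083).

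The comparison of MG with AG, both in flight and from 1 supplier, asks what gravity changed among mice that had flown. No single gene passed the threshold. Interferon, antigen presentation, heat shock, bile duct, erythroid and macrophage genes lay lower in MG than in AG as lists, as did male-biased genes and fatty acid and triglyceride synthesis genes, and acute phase genes lay higher. These are camera calls with a preset correlation, and 0 of the 16 lists called held with an estimated correlation (smallest adjusted p = 0.323). Krt19, a keratin of bile duct cells, averaged 2.22 ± 0.15 CPM (SD, n = 3) in MG and 12.2 ± 7.97 CPM (SD, n = 3) in AG, without passing the test.

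In edgeR's quasi-likelihood test 0 genes were changed in MG vs AG, with 1165 genes at an unadjusted p below 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.0606. DESeq2 called 97, limma-voom 2 (Erbb3 and Peg3), edgeR's robust setting 8, edgeR's exact test without a filter 90, and the authors' deposited table marks 60. The libraries did not overlap for 12.4% of genes, where chance gives 10%. The 5 genes with the smallest p, none of them called, were the receptor gene Erbb3 (0.72 ± 0.09), the imprinted gene Peg3 (1.06 ± 0.14), Cyp4a12b (-1.26 ± 0.18), the carboxylesterase Ces2c (-1.46 ± 0.20) and 1500017E21Rik (-2.28 ± 0.34). Of the fixed genes, Fgf21 stood at 1.29 ± 0.57, Cyp4a14 at 0.66 ± 0.37, Nnt at 0.36 ± 0.09, Cyp2b10 at 0.33 ± 0.67, Saa1 at 0.30 ± 0.60, Gclc at 0.23 ± 0.17, Cbs at 0.19 ± 0.12, Cdkn1a at 0.04 ± 0.69, Pck1 at -0.06 ± 0.23, Per2 at -0.44 ± 0.16, Cyp7a1 at -0.93 ± 0.68 and Col1a1 at -0.95 ± 0.44. The count was 130 without AG 3, 7 without AG 1, 6 without GC 2 and 0 in the other 6 fits that left out 1 library.

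By camera, 16 of 38 lists were called in MG vs AG, 3 upward and 13 downward, and 0 with an estimated correlation. Over all genes, 0 members were called in any of them. All 24 interferon response genes had negative values with a median of -0.59, and 0 passed when adjusted over the list alone (camera adjusted p = 1.19e-07, and adjusted p = 0.427 with an estimated correlation). Gbp3 stood at -1.31 ± 0.41. In 17 antigen presentation genes, all negative, 4 were lower when adjusted over the list alone (camera adjusted p = 7.67e-06, and adjusted p = 0.427 with an estimated correlation). H2-Q6 stood at -0.76 ± 0.17. The library means of this list overlapped: they were 0.41, 0.12 and -0.15 in AG 1 to AG 3, and -0.55, -0.31 and -0.02 in MG 1 to MG 3. In 15 heat shock genes 8 were lower when adjusted over the list alone (camera adjusted p = 6.26e-05, and adjusted p = 0.427 with an estimated correlation). Hspa1b stood at -3.20 ± 0.72. The mean of the heat shock list was 0.465 in AG 1 and 0.394 in AG 2, but -0.252 in AG 3, within the MG range of -0.311 to -0.189. In 22 acute phase genes 5 were higher when adjusted over the list alone (camera adjusted p = 0.00174, and adjusted p = 0.552 with an estimated correlation). Hp stood at 0.64 ± 0.13 and Itih4 at 0.50 ± 0.14. The interferon list averaged 0.85 in AG 1, the library rich in macrophage transcripts, against 0.03 in AG 2 and -0.14 in AG 3. The MG libraries lay lower than all of these, at -0.37 to -0.23. Without AG 1 camera still called the list lower (adjusted p = 0.0011), and a link to macrophages was not tested.

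In 14 male-biased genes 9 were lower in MG than in AG when adjusted over the list alone, with a median of -0.72 (camera adjusted p = 1.19e-07, and adjusted p = 0.323 with an estimated correlation). Ugt2b38 stood at -1.95 ± 0.36. In 8 female-biased genes 0 passed when adjusted over the list alone (camera adjusted p = 0.0145 upward, and adjusted p = 0.552 with an estimated correlation). In 18 genes of fatty acid and triglyceride synthesis 2 were lower when adjusted over the list alone (camera adjusted p = 0.000187, and adjusted p = 0.427 with an estimated correlation). Scd1 stood at -1.72 ± 0.29 and Elovl6 at -1.10 ± 0.22. The 24 genes of cholesterol synthesis and uptake were not called as a list, and 0 passed when adjusted over the list alone (camera adjusted p = 0.0549, and adjusted p = 0.769 with an estimated correlation). The adjusted p of that list by camera ranged from 2.17e-05 without AG 1 to 0.932 without AG 3 over 15 alternatives, and it was 0.00204 without GC 1, GC 2 and MG 2. In MG vs AG it also passed the threshold without GC 1 (0.0342), GC 3 (0.00981) or MG 2 (0.029). In 27 genes of fatty acid oxidation 0 passed when adjusted over the list alone (camera adjusted p = 0.00471 upward, and adjusted p = 0.659 with an estimated correlation). In 25 Nrf2 targets 6 were lower when adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.404 with an estimated correlation). Gsta1 stood at -3.25 ± 0.55. In 13 mitochondrially encoded genes 0 passed when adjusted over the list alone (camera adjusted p = 0.000471, and adjusted p = 0.522 with an estimated correlation).

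Cell type markers also separated MG from AG as lists. In 7 bile duct markers 5 were lower in MG when adjusted over the list alone (camera adjusted p = 7.67e-06, and adjusted p = 0.323 with an estimated correlation). Muc1 stood at -3.22 ± 0.62 and Krt7 at -1.80 ± 0.46. In 6 erythroid genes 5 were lower when adjusted over the list alone (camera adjusted p = 7.87e-06, and adjusted p = 0.323 with an estimated correlation). Hba-a1 stood at -1.26 ± 0.26. In 12 macrophage markers 9 were lower when adjusted over the list alone (camera adjusted p = 7.67e-06, and adjusted p = 0.427 with an estimated correlation), again with AG 1 highest. In 22 extracellular matrix genes 0 passed when adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.576 with an estimated correlation). In 17 cell cycle genes 1, Ccnd1, was lower when adjusted over the list alone (camera adjusted p = 0.0391, and adjusted p = 0.522 with an estimated correlation). In 19 circadian clock genes 4, Bhlhe40, Ciart, Usp2 and Nr1d1, were lower when adjusted over the list alone (camera adjusted p = 0.0391, and adjusted p = 0.427 with an estimated correlation).

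Without AG 1, 12 of the 16 list calls in MG vs AG remained. Camera then gave adjusted p = 0.217 for extracellular matrix (range over 15 alternatives 6.43e-07 to 0.217), 0.282 for cell cycle (0.0142 to 0.282), 0.0548 for circadian clock (0.0198 to 0.237) and 0.154 for female-biased genes (5.92e-05 to 0.213). Other calls that ended by camera were those of acute phase genes without MG 1 (adjusted p = 0.0708, range 1.5e-05 to 0.0708), fatty acid oxidation without MG 2 (0.337, range 3.83e-08 to 0.357) and mitochondrially encoded genes without AG 3 (0.217, range 7.9e-06 to 0.217). Those of cell cycle (0.0508 without GC 3, 0.175 without MG 1, 0.0527 without MG 2), circadian clock (0.0554 without GC 3, 0.0687 without MG 3, 0.237 without AG 2), extracellular matrix (0.0908 without MG 1) and female-biased genes (0.139 without MG 2, 0.0981 without AG 2) ended without other libraries too.

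The AG values of the genes changed in MG vs GC show where the centrifuge mice lay between the other groups. Of the 165 genes, 164 lay on the same side of GC in AG as in MG, and the AG mean stood at a median of 0.556 of the way from GC to MG on the log2 scale (quartiles 0.4 and 0.721). AG lay nearer to GC than to MG for 65 genes (39.4%) and beyond MG for 4. Scd1, with 3956 ± 1548 CPM in AG (SD, n = 3), lay between both groups, and Gsta1 was the 1 gene on the other side of GC. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 165 genes, MG differed from AG for 88 and AG from GC for 118, 41 of them in both. The same MG and GC libraries chose these genes, so neither count nor the shared side of GC is free of that choice, and over all genes AG vs GC had 0 calls. In 20 simulations in which AG had the same mean as GC, also added after seeing the data, 71.9% of called genes lay on the same side on average (76.3% at most, against 99.4% here). AG then differed from GC for 1.12% of them on average and 4.13% at most, against 71.5% here, and the median ratio averaged 0.152. A ratio under 1 also arises because the genes were chosen on their MG values. In 20 simulations in which MG and AG had the same mean, added after seeing the data, the median ratio averaged 0.865 (0.823 to 0.904) and MG differed from AG for 1.18% of called genes on average and 5.81% at most. Here the share was 53.3%. Both sets of simulations drew genes independently of each other, while genes in these libraries move together, as in the cholesterol list (estimated correlation 0.752). The simulated shares therefore vary too little between runs, and the highest of 20 does not bound what groups with equal means would give. Both sets also took observed means as true means. They called more genes than the 165 here, on average 318 with AG equal to GC and 298 with MG equal to AG. The choice of genes can thus weigh less in them, and their ratios of 0.152 and 0.865 are not matched to the 0.556 here. With the groups exchanged, the 165 genes with the smallest p in AG vs GC, 0 of them called, had MG at a median of 0.945 of the way to AG. The ratio was 0.46 without GC 2 and 0.618 without AG 2, the lowest and highest of the 9 fits that left out 1 library.

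**Figure D4:**
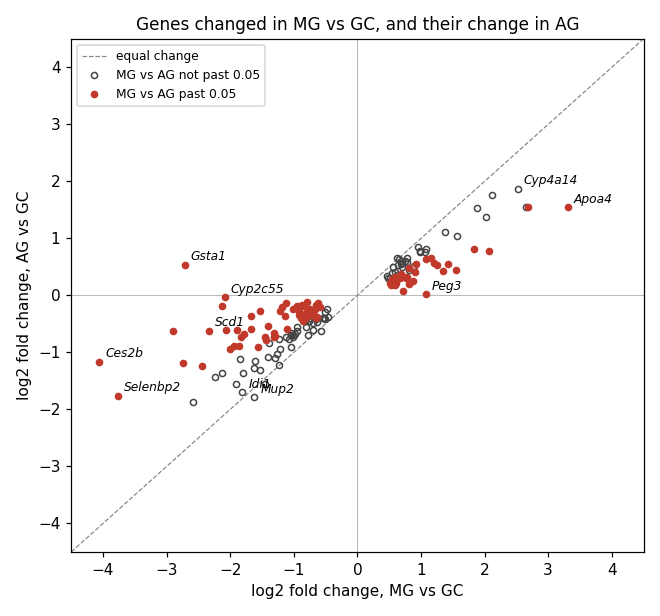
Log2 fold changes in MG vs GC (x axis) and AG vs GC (y axis) of the 165 genes changed in MG vs GC. Each point is a gene, filled for the 88 genes that differ between MG and AG when adjusted over the 165, and the dashed line marks equal change; 164 points lie in the quadrants of equal sign.

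Across all 11884 genes the log2 fold changes of MG vs GC and AG vs GC had a Pearson correlation of 0.429 and a Spearman correlation of 0.474, across genes, which are not independent replicates. Both comparisons use the same 3 GC libraries, and 20 simulations with unchanged groups gave a mean Pearson correlation of 0.502 (0.449 to 0.556). The observed Pearson correlation was thus below all of these simulations and shows no agreement beyond the shared libraries. The covariance was 0.0727, and the simulated covariance 0.0519 on average (0.0464 to 0.0607), a difference of 0.0208. At an unadjusted p below 0.05, 242 genes were higher in both comparisons, against 47.6 for independent lists and 70.4 in the simulations, and 277 were lower in both, against 35.9 and 57.3. The simulated overlaps arose from fewer genes, a mean of 289 and 276 higher against 864 and 655 observed, for which independent lists would share 6.73. Part of the excess may come from the shared controls. With separate GC libraries for each comparison, 1 for one and 2 for the other in 6 ways, a test added after seeing the data, log2 CPM differences had a mean correlation of 0.172 (0.0127 to 0.305), against 0.532 with shared libraries. It was lowest where GC 3 alone served 1 of the comparisons, at 0.0127 and 0.0651, and the mean covariance was 0.0291, against 0.0686 with shared libraries.

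The mean of both flight groups against GC asks what flight, transport and supplier did together. In edgeR's quasi-likelihood test 42 genes rose and 77 fell at a Benjamini-Hochberg adjusted p below 0.05, 48 of the 119 at least 2-fold, and the libraries did not overlap for 111 of the 119. Of all genes 6.99% did not overlap, where chance gives 2.38%. Of 24 cholesterol synthesis and uptake genes 7 fell and 17 were not called, with 17 lower when adjusted over the list alone (camera adjusted p = 5.23e-15, and adjusted p = 0.477 with an estimated correlation). Of 18 fatty acid and triglyceride synthesis genes 8 fell and 10 were not called, with 11 lower when adjusted over the list alone (camera adjusted p = 3.5e-09, and adjusted p = 0.297 with an estimated correlation). Of 14 male-biased genes Cyp4a12b, Cyp2d9, Cyp7b1 and C6 fell and 10 were not called, with 12 lower when adjusted over the list alone (camera adjusted p = 5.8e-14, and adjusted p = 0.267 with an estimated correlation). Camera called 15 lists, 7 upward and 8 downward, 0 of them with an estimated correlation.

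Other lists shifted in flight vs GC included fatty acid oxidation, where Cyp4a14, Cyp4a31, Vnn1 and Cd36 rose, Fabp1 fell and 22 of 27 genes were not called, with 9 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4.27e-07, and adjusted p = 0.579 with an estimated correlation). Of 18 glucocorticoid and stress hormone genes Hsd11b1 rose and 17 were not called, with 5 higher when adjusted over the list alone (camera adjusted p = 6.35e-05, and adjusted p = 0.297 with an estimated correlation). Of 8 female-biased genes Acot3 and Abcd2 rose and 6 were not called, with 5 higher when adjusted over the list alone (camera adjusted p = 0.000289, and adjusted p = 0.578 with an estimated correlation). Of 25 nuclear oxidative phosphorylation genes Ndufb3 and Cox5b fell and 23 were not called, with 3 lower when adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.579 with an estimated correlation).

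The count in flight vs GC was 13 without GC 1, 0 without GC 2, 0 without GC 3, 56 without MG 2, 47 without MG 3 and 229 without AG 3, and 13 when MG and AG were treated as 1 group, a model added after seeing the data. It was also 0 without GC 1, GC 2 and MG 2 together.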

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

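The tests of muscle genes in 3 libraries, of gravity as the source of muscle transcripts and of Kupffer cells were chosen after the result was seen.

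Of the 165 genes changed in MG vs GC, 88 also differed between MG and AG when adjusted over those genes, which marks a difference between both flight groups under the same contrast with the ground. The 165 were chosen with the same MG libraries that enter the second test. The markers of bile duct cells differed in the same way: their median log2 fold change in MG vs AG was -1.16, with all 7 values negative and an adjusted p of 0.0408 in fry, but camera with an estimated correlation gave an adjusted p of 0.323. In unique intron reads, which the comparisons of the report do not use, 64 genes changed in MG vs GC, 31 higher and 33 lower, in edgeR's quasi-likelihood test.

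Skeletal muscle transcripts were present in some libraries of every group. In each of the 3 groups some libraries lay above and others below the mean of the muscle list, which argues against the gravity condition as the source. Of 19 further muscle genes, 12 had their highest levels in GC 1, GC 2, MG 2 and AG 1, too few for the share set beforehand, while 17 had them in GC 1, GC 2 and MG 2, which is consistent with muscle tissue carried over into these 3 libraries. Without these libraries, the fold changes of the genes changed in MG vs GC were 0.973 of the full ones in the median. That ratio cannot decide whether muscle gave the changes, because genes whose MG and GC libraries lie apart tend to keep their fold changes. With the muscle markers as a covariate, edgeR called 162 genes in MG vs GC, against 165 without it. How muscle entered the samples stays open.

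Macrophage genes stood out in AG 1, with Marco at 278 CPM against a mean of 3.89 in the other 8 libraries and Spic at 27.4 against 1.25. Of other Kupffer cell genes, Timd4 was at 5.26 times its mean in the others, Cd5l at 7.21 and Vsig4 at 1.71, but Clec4f at 0.984 and Cd163 at 1.13, which argues against more Kupffer cells with an unchanged profile as the whole source and leaves Kupffer cells with changed expression open. Of 8 genes of the peritoneal cavity 0 were at least 4 times higher in AG 1, with Gata6 at 19.2 CPM against 17.6, although Gata6, Prg4 and Fn1 have a liver level that can hide a small share. Of 11 spleen genes, 6 were at least 4 times higher, among them Ighm and Cd79b at low levels, while the abundant Cd74 was at 98 CPM against 68.4, so spleen tissue cannot be told apart from another macrophage population. A response of this animal to flight or centrifugation was not tested.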

How the results depend on the processing

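Alternatives added after seeing the data were unique and total exon reads, the exact test, the muscle covariate, leaving out 3 libraries, flight as 1 group and the GC content and length correction. Under the settings applied to named genes, 33 of 5161 fold changes differed in sign, all of them for genes not called. Leaving out libraries could not turn the sign of called genes whose libraries do not overlap. For MG vs GC, 165 genes became 278 without a filter, 390 by DESeq2, 375 with only the groups compared, 29 at an adjusted p below 0.01, 79 at 2-fold, 494 by the exact test and 0 without GC 1, GC 2 and MG 2, where 1 GC library was left. For AG vs GC, 0 became 44 without a filter, 118 by DESeq2, 4 with only the groups compared (Mup1, Mup2, Mup16 and Serpina1e), 73 by the exact test and 2 with the muscle covariate (Mup1 and Pmvk). For MG vs AG, 0 became 38 without a filter, 97 by DESeq2, 2 by limma-voom, 8 with the robust setting, 1 with only the groups compared (Dmbt1) and 90 by the exact test. For flight vs GC, 119 became 215 without a filter, 322 by DESeq2, 0 at an adjusted p below 0.01, 48 at 2-fold, 0 without the 3 libraries and 13 with flight as 1 group. List calls fell to 0 in every comparison by camera with an estimated correlation. Fry called 4 (MG vs GC), 0 (AG vs GC), 1 (MG vs AG) and 2 (flight vs GC). The 4 were substrain genes (fry adjusted p = 0.00323), male-biased genes (0.00343), and fatty acid and triglyceride synthesis and lipoprotein genes (0.0229 each). Camera had not called the lipoprotein list. The correlation of MG vs GC with AG vs GC was 0.517 at a mean count of at least 50. Leaving out 1 library gave 21 to 290 genes for MG vs GC, 0 to 60 for AG vs GC, 0 to 130 for MG vs AG and 0 to 229 for flight vs GC, 17 to 21, 9 to 17, 13 to 20 and 12 to 16 lists, correlations of 0.322 to 0.518 and AG positions of 0.46 to 0.618. Of 49 named calls, 6 held in all 9 such fits and the others in 2 to 8. Stricter thresholds call fewer genes by construction. For the other settings the cause was not tested. At this depth and number of libraries, 15.2% to 23.5% of simulated 1.5-fold changes were recovered.

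With the replicate number as a block, 158 genes were called in MG vs GC, 0 in AG vs GC, 1 in MG vs AG (Ces2c) and 130 in flight vs GC, and 17, 10, 17 and 16 lists. The numbers do not pair the libraries: deviations of same-numbered libraries correlated above 0.1 in 5 of 9 pairs (-0.283 to 0.48), and 4 of 9 libraries were closest to their own number.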

Other observations

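The test of the supplier was chosen after the result was seen.

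Intron reads were also tested in MG vs GC, and the genes named here were chosen after their values were seen. Among the 64 genes changed there in edgeR's quasi-likelihood test, 23 were also called in exons, among them Wsb1, Mup11 and Fasn, and 41 were not. Some of the 41, such as Nxph1, were not tested in exons. Wsb1 rose by 2.04 ± 0.20 on the log2 scale, Igfbp1, an insulin-like growth factor binding protein, by 2.59 ± 0.35, the insulin receptor substrate Irs2 by 1.73 ± 0.26, Got1 by 1.98 ± 0.30 (but -0.03 in exons, not called) and the monooxygenases Fmo1 and Fmo2 by 1.23 ± 0.14 and 2.02 ± 0.23. The major urinary protein genes Mup7 (-3.63 ± 0.43) and Mup11 (-1.59 ± 0.20), which are near copies of each other, and Fasn (-2.84 ± 0.44) fell. Like Got1, the genes Igfbp1, Irs2, Fmo1, Fmo2 and Mup7 were not called in exons. In MG vs AG 1 gene changed in intron reads, Wsb1 (1.67), and in AG vs GC 0 did in the same edgeR test, with 831 at an unadjusted p below 0.05. Of 137 genes called in exons and tested in introns, 92.7% had the same sign in introns, against 63.4% of all genes. Changes present before splicing would give this, but the shares do not establish them. They come from the same libraries and are not matched for size of change. Reads counted in introns are also not from unspliced transcripts alone. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2, which have no introns, held 1108658 to 1748264 of them per library. Among the 137, mt-Nd4 stood at 0.12 in introns and -0.92 in exons.

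In MG vs GC camera called male-biased genes lower and female-biased genes higher, with 10 of 14 and 2 of 8 called, but neither with an estimated correlation (adjusted p = 0.219 and 0.359). Only 8 of the 16 female-biased genes listed were tested. By fry the adjusted p was 0.00343 for male-biased and 0.0885 for female-biased genes. Shared reads between paralogs and GC content or transcript length are argued against as the whole cause, since the median of the male-biased list was -1.04 in unique exon reads and -1.06 after correction. The supplier of the mice as the whole cause allows no difference between both flight groups, from 1 supplier, where the list median was -0.717, with 9 of 14 genes lower when adjusted over the list alone and library means of -0.83 to -0.46 in MG and -0.18 to 0.33 in AG. It is left open because fry gave that list an adjusted p of 0.0603 and camera 0.323 with an estimated correlation. A candidate explanation is a more continuous release of growth hormone, which would lower Bcl6, but its log2 fold change of 0.322 ± 0.705 is too wide to decide, and food intake, stress at landing and gravity itself were not tested.

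With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The 165 genes of MG vs GC were reached by 1 of 10 splits, the real one, with 37 the highest other, and the 17 lists by 1, with 14 the highest other. For AG vs GC all 10 splits gave at least as many as the real 0 genes, with 0 the highest other, and 8 gave as many as the real 11 lists, with 17 the highest other. For MG vs AG these were 10 splits, 0 genes and 0 the highest other, and 3 splits for the real 16 lists, with 17 the highest other. For flight vs GC, 2 of 84 splits, the real one included, gave as many as the real 13 genes of the model with flight as 1 group. That share is under 0.05, but a wrong split called more genes, so chance is made less likely and not excluded. This highest other, 28, came from the split that sets GC 1, GC 2 and MG 2, the libraries richest in muscle transcripts, against the rest. The 15 lists called there were matched by 21 of 84 splits, with 21 the highest other, so chance is not excluded for the number of lists.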
